A study of Homo sapiens with 3 samples.

How the data were processed

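RNA was measured in 3 stable KYSE30 lines: 1 control line and 2 lines with different shRNAs against SNORD12B, with 1 library each. Per the labels' protocols, cells grown with 10% serum were exposed to virus for 24 hours and selected with 5 ug/mL blasticidin for 2 weeks, and total RNA was extracted with Trizol. The deposited table holds raw counts per gene, which the authors made with featureCounts 1.6.4 against an hg38 annotation, per the file headers. Those headers give the strand option as 1 and no paired-end option. Per the submitters' processing notes, TopHat2, HTSeq and hg19 were used, which differs from the file headers. All 52179 gene identifiers that the table shares with GENCODE 29 in the same version have the same start and end there, so coordinates are given in hg38. The library kit is not given in the sources used here. The median antisense gene carried 1.58 times the count that reads of the gene opposite it predict, with 46.5 percent of such genes within 2-fold of that prediction, so genes that overlap on opposite strands are treated as uncertain.

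The table lists 60554 genes, of which 56558 matched a gene name table by identifier. Total counts were 15473922, 15146805 and 17336936 in the control and the libraries labelled shRNA 1 and shRNA 2, and 25058, 24986 and 25270 genes had at least 1 count. Mitochondrial genes took 4.6, 3.94 and 4.25 percent of the counts. Intervals of counts are exact Poisson intervals at 95 percent, ratios of counts have exact conditional intervals, and a count of 0 is given the limit of 3 counts. All of these cover counting error only.

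Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes passing filterByExpr (17801) were scaled by TMM on the totals of all genes in the table (factors 0.993, 1.004 and 1.003). The 2 shRNA lines were compared with the control by edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment at 0.05. The SE given with a log2 fold change is its absolute value over the square root of that test's F statistic. It is thus worked back from the test and does not come from replicate cultures. The fit had 1 residual degree of freedom and 8.35 prior degrees of freedom, and a common biological coefficient of variation of 26.7 percent. Log2 ratios of single libraries use log-CPM with a prior count of 2 and have no test. The value that a shared control gives by itself came from 50 simulations of 3 unchanged libraries.

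Before the data were examined, 35 gene lists, the tests and the rule for named genes were fixed. Of the lists, 30 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, beside an estimated correlation and fry. The test with an estimated correlation rests on the 1 residual degree of freedom, so a call lost there does not decide against a list. Each list's median was also ranked among 10000 random lists of the same size matched on mean expression. The rule names the SNORD12B locus genes and 12 higher and 12 lower genes with an official symbol and at least 5 CPM where higher. As no gene passed the adjusted threshold, these are the genes with the largest smaller log2 ratio of the pair. It further names up to 4 members per list with at least 1 CPM and the largest log2 fold change, the 2 highest and 2 lowest ratios between the shRNA libraries among genes with at least 20 CPM, and PPP1CA, AKT1, MTOR, EIF4EBP1 and EIF4E.

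The test was checked on simulated data for the comparison of knockdown with control. Among about 17347 genes in each of 5 draws, it recovered 81.8 percent of 100 genes changed 4-fold and 100 percent of 100 genes changed 16-fold, with 12.4 false calls per draw. The changed genes were all drawn from those with a mean of at least 5 CPM and had the same fold in both shRNA lines. Recovery of lower genes, or of changes that differ between the lines, was not tested. The simulation used the trended spread only and gave genes no spread of their own. Alternatives covered the scaling, the test, the filter on low counts, the library size, a fold threshold, the prior count and leaving out each shRNA line. With DESeq2, the likelihood ratio test and the fold threshold, lists were tested by the preranked form of camera on signed scores of the gene test, not on log-CPM. Other settings were added after the data were seen: library sizes of filtered genes, genes without opposite-strand overlap and counts thinned to equal depth. The number of list members on the same side of the control in 50 simulations of unchanged libraries, with genes drawn independently, was added then too.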

Results

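Gene expression was measured by RNA sequencing in KYSE30, an established human esophageal squamous cell carcinoma line. The design asks what differs when SNORD12B, a box C/D small nucleolar RNA, is depleted. RNAs of this class guide the methylation of ribosomal RNA. There were 3 stable cell lines with 1 library each: 1 control line and 2 lines with different shRNAs against SNORD12B. The genotype label calls the control a vector, whereas the protocol describes a non-targeting scrambled shRNA. Total counts were 15473922 in the control, 15146805 in the library labelled shRNA 1 and 17336936 in the library labelled shRNA 2. No line had a replicate culture. The p-values of single genes thus measure only the spread between the 2 shRNA lines, and the lone control is assumed to vary like them. Those of gene lists by camera with the preset correlation compare the members with all other genes. They do not measure how far cultures vary. Fry called 0 lists.

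SNORD12B was counted 7 times in the control, 15 times in the library labelled shRNA 1 and 1 time in the library labelled shRNA 2. The gene (ENSG00000222365.1) lies on chromosome 20 from 49280319 to 49280409 on the plus strand of hg38, spans 91 nucleotides and sits within its host gene ZFAS1. Its level was 0.456 CPM in the control (95% exact Poisson interval 0.183 to 0.939), 0.986 CPM (0.552 to 1.63) with the label shRNA 1 and 0.0575 CPM (0.00146 to 0.32) with the label shRNA 2. Relative to the control, the count ratio was 2.16 (exact interval 0.831 to 6.28) for the library labelled shRNA 1 and 0.126 (0.0028 to 0.982) for the library labelled shRNA 2. These intervals cover counting error only. The library labelled shRNA 1 thus showed no lower SNORD12B count, which goes against its label as far as these reads go. So few counts of a short RNA cannot settle whether the knockdown held. With 1 count and an upper bound of 0.982 on its ratio, the library labelled shRNA 2 is hardly better checked. Each direction given below for both shRNAs thus rests on libraries whose knockdown is unchecked. The neighbouring SNORD12 was counted 0 times in each library, which allows up to 0.195 CPM in the control. SNORD12C was counted 2, 2 and 0 times in the control and the libraries labelled shRNA 1 and shRNA 2. ZFAS1, the long non-coding host RNA, stood at 12.1, 14.2 and 9.49 CPM in the same order, and ZNFX1, the neighbouring gene on the minus strand, at 190.5, 181.6 and 246.9 CPM. ZFAS1 is overlapped on 11.1% of its exonic bases on the opposite strand, with ZNFX1 as partner, so its level is uncertain.

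The genes lowest relative to the control with both shRNAs included SESN3, which encodes a stress-induced sestrin, and SLC2A3, which encodes the glucose transporter GLUT3. SESN3 (ENSG00000149212.11, chromosome 11, 95165513 to 95232541) stood at 12.6 CPM in the control, against 0.329 CPM in the library labelled shRNA 1 and 0.632 CPM in the library labelled shRNA 2. SLC2A3 stood at 24.8 CPM in the control and at 0.3945 and 1.84 CPM with the labels shRNA 1 and shRNA 2. FGFR2, a receptor for fibroblast growth factors, stood at 10.4 CPM in the control and at 1.05 and 1.84 CPM. Low counts limit several of these ratios. TCIM had 96 counts in the control but 2 and 3 in the shRNA libraries, giving ratios of 0.021 (exact interval 0.00251 to 0.0781) and 0.0276 (0.00559 to 0.0831). MARK1 and VIT each had 3 counts in the library labelled shRNA 1, with ratios to the control of 0.0191 (0.00389 to 0.0567) and 0.018 (0.00368 to 0.0536). The other genes chosen by the same rule were NREP, FREM2, KLHL13, C1orf21, IGFBP5 and the keratin pseudogene KRT16P6, whose reads cannot be separated with certainty from KRT16. Log2 fold changes of the pair of shRNA lines to the control were -4.67 for SESN3 (SE 0.57) and -4.44 for SLC2A3 (SE 0.64), with adjusted p = 0.121 and 0.211 in edgeR's quasi-likelihood test. None of these 12 genes passed the adjusted threshold in that test, whereas DESeq2 called TCIM, SESN3, SLC2A3, MARK1, NREP, VIT, FREM2 and C1orf21 lower. The likelihood ratio test of edgeR, and its quasi-likelihood test with no filter beyond a count above 0, called all 12 lower.

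The genes highest relative to the control included VIM and CDH2, which encode the mesenchymal proteins vimentin and N-cadherin, and COL5A1, a fibrillar collagen chain. VIM (ENSG00000026025.13, chromosome 10, 17228259 to 17237593) stood at 4.75 CPM in the control, 67.3 CPM in the library labelled shRNA 1 and 17.4 CPM in the library labelled shRNA 2. CDH2 stood at 1.56, 10.2 and 4.71 CPM in the same order, and COL5A1 at 2.21, 13.1 and 9.54 CPM. CEACAM6, a cell adhesion glycoprotein, stood at 15.3 CPM in the control against 37.9 and 39.6 CPM. TLR4, a receptor for bacterial lipopolysaccharide, stood at 4.82 CPM against 17.3 and 12.3 CPM. The rule also took ANOS1, CYP4V2, EPHB6, LVRN, XAF1, KLHL29 and VIM-AS1. VIM-AS1 shares 32.18% of its exonic bases with exons on the opposite strand and VIM shares 25.38%, each being the other's partner, so the count of VIM-AS1 in particular is uncertain. XAF1 is overlapped on 38.32% of its exonic bases. The log2 fold change was 3.15 (SE 0.77) for VIM and 2.35 (SE 0.52) for COL5A1, with adjusted p = 1 and 0.93 by edgeR, and none of the 12 genes passed. The likelihood ratio test of edgeR called COL5A1 and VIM, and the quasi-likelihood test with no filter called COL5A1, VIM and VIM-AS1.

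**Figure D1:**
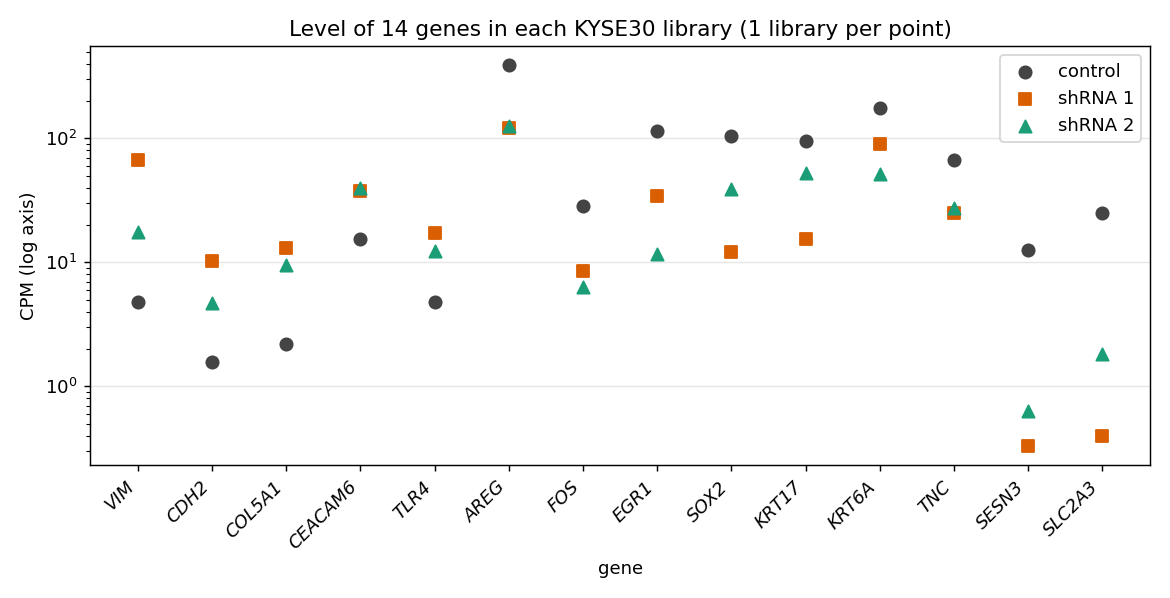
Level of 14 genes in CPM (log axis) in the control library and the libraries labelled shRNA 1 and shRNA 2, with 1 point per library and no error bars. AREG lay at 387.5 CPM in the control and at 122 and 125.2 CPM in the shRNA libraries, while VIM lay at 4.75, 67.3 and 17.4 CPM.

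Across 17801 tested genes, edgeR's quasi-likelihood test called 0 genes higher and 0 genes lower at an adjusted p under 0.05. At an unadjusted p under 0.05, 73 genes were higher and 164 lower, where 890 would be expected by chance alone. The spread in this test comes from the 2 shRNA lines alone, which lay further from each other than from the control. A count below that expected by chance thus marks a strict test, so 0 calls do not show that no gene changed. DESeq2 called 0 higher and 14 lower, limma-voom 0 and 1, and edgeR's likelihood ratio test 2 and 36. With no filter beyond a count above 0, the quasi-likelihood test called 4 and 37. The smallest adjusted p in edgeR's quasi-likelihood test, 0.0523, belonged to ENSG00000275266, which has no official symbol and is named here after its values were seen. This short RNA lies inside H19 on the opposite strand, so its reads cannot be told from those of H19 if strands were not separated, and it had 846, 64 and 46 counts in the control and the libraries labelled shRNA 1 and shRNA 2; H19 had 5068, 377 and 1287. The spread rests on 1 residual degree of freedom, and when each library was thinned to 99 percent of its reads in 10 draws, the number of calls lay between 1 and 6.

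At least 2-fold higher with both shRNAs were 174 genes, and 212 were at least 2-fold lower, a description of size with no test. The same count with another library in the control's place was larger. It was 873 genes in all for the library labelled shRNA 1 and 460 for the library labelled shRNA 2, against 386 for the control. Taken alone, the library labelled shRNA 1 had 665 genes at least 2-fold higher and 994 at least 2-fold lower than the control, and the library labelled shRNA 2 had 531 and 616. Independent lists of these sizes would share 19.8 and 34.4 genes, while 3 unchanged libraries simulated with the fitted spread gave 377.2 and 219.5 on average, because both ratios share the control. Neither count of genes shared by both shRNAs exceeded what unchanged libraries gave, with a simulated range of 338 to 412 higher and 187 to 247 lower. The fitted spread comes from the 2 shRNA lines alone, which lay further from each other than from the control. It is thus a wide yardstick: the 174 higher genes lay below its whole range, so it cannot exclude changes shared by both shRNAs. Across genes, which are not independent replicates, the 2 sets of log2 ratios had Pearson's r = 0.34 and Spearman's rho = 0.199. Simulated unchanged libraries gave 0.502 and 0.477, and the covariance was 0.113 against a simulated 0.204. The observed values lay below the simulated ones, whose spread comes from the shRNA lines, and decide nothing on shared changes.

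Genes that report signalling from the epidermal growth factor receptor through MAP kinases were lower with both shRNAs. Of 20 measured members, 14 lay below the control in both shRNA libraries and 1 above it in both, with median log2 ratios of -0.43 (label shRNA 1) and -0.38 (label shRNA 2). In simulated unchanged libraries that share 1 control, with genes drawn independently, 6.5 members lay below it in both on average (2 to 10). The camera test gave adjusted p = 2.03e-05 with a preset correlation of 0.01, and adjusted p = 0.988 with an estimated correlation. That estimate was -0.042, below the preset one, and the test with it rests on 1 residual degree of freedom. AREG, which encodes the receptor ligand amphiregulin, stood at 387.5 CPM in the control and at 123.6 ± 2.25 CPM in the libraries labelled shRNA 1 and shRNA 2 (SD, n = 2). The immediate early genes FOS and EGR1 stood at 28.4 and 113.9 CPM in the control. FOS lay at 8.48 and 6.32 CPM and EGR1 at 34.5 and 11.6 CPM in the libraries labelled shRNA 1 and shRNA 2. ETV5 had a log2 fold change of -0.92 (SE 0.35). Adjusted over the list alone, AREG, FOS and EGR1 passed in edgeR's quasi-likelihood test with adjusted p = 0.00488, 0.00665 and 0.0102, and 0 members passed over all genes. Over all genes, DESeq2 called AREG lower, and both the likelihood ratio test and the quasi-likelihood test with no filter called AREG, FOS and EGR1 lower. The SNORD12B count was not lower in the library labelled shRNA 1, which is 1 of the pair behind these directions.

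Genes of basal squamous epithelium were lower as well. Of 13 measured members, 11 lay below the control in both shRNA libraries and 1 above it in both, with median log2 ratios of -0.96 and -0.36 for the labels shRNA 1 and shRNA 2. The simulated number below in both was 4.8 (1 to 9). KRT5 and KRT6C, also on this list of 15 genes, did not pass the filter on low counts. SOX2, a transcription factor of the basal layer of the esophagus, stood at 104.1 CPM in the control and at 12.2 and 38.9 CPM in the libraries labelled shRNA 1 and shRNA 2. KRT6A stood at 174.7, 90.1 and 51.4 CPM, KRT17 at 94.6, 15.45 and 52.95 CPM and NGFR at 26.2, 4.67 and 13.3 CPM in the same order. Reads from KRT6A and KRT17 may be shared with near-identical keratin genes, and NGFR is overlapped by an antisense gene on 27.13% of its exonic bases. Camera gave adjusted p = 6.67e-06 with the preset correlation and adjusted p = 0.988 with an estimated correlation. SOX2 and KRT6A passed when adjusted over the list alone, both with adjusted p = 0.0387 by edgeR, and 0 members passed over all genes. With no filter, the quasi-likelihood test called SOX2 and KRT17 lower over all genes. Here too the library labelled shRNA 1 had no lower SNORD12B count.

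Mesenchymal genes were higher on balance in the library labelled shRNA 1, with a median log2 ratio of 0.59, and lay at 0.06 in the library labelled shRNA 2. Of 16 measured members, 8 were above the control in both libraries and 3 below it in both, where unchanged libraries gave 5.8 (2 to 11) above in both. VIM and CDH2 passed when adjusted over the list alone (adjusted p = 0.0235 and 0.0378 by edgeR), and so did TNC in the opposite direction (adjusted p = 0.0235). Over all genes 0 members passed, whereas the likelihood ratio test and the quasi-likelihood test with no filter called VIM. TNC, which encodes the matrix protein tenascin-C, stood at 66.7 CPM in the control and at 26.4 ± 1.71 CPM (SD, n = 2) in the libraries labelled shRNA 1 and shRNA 2, the first of which had no lower SNORD12B count. ZEB1 had a log2 fold change of 1.47 (SE 0.64). Camera gave adjusted p = 0.0272 for the list with the preset correlation. It gave adjusted p = 0.988 with an estimated correlation, a test that rests on 1 residual degree of freedom.

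Inflammatory, hypoxia and ribosomal protein genes were the other groups with the same sign in both shRNA libraries among the 8 that camera called. Of 16 NF-kB and cytokine genes, 10 were below the control in both and 1 above it in both, against a simulated 5.1 (2 to 9) below in both. PTGS2, the inducible cyclooxygenase, stood at 11.1 CPM in the control against 2.83 and 2.99 CPM, and alone passed when adjusted over the list (adjusted p = 0.0301 by edgeR). CXCL8 stood at 31.4 CPM against 13.55 and 13.1 CPM. Of 14 hypoxia genes, 10 were below the control in both shRNA libraries, including ANGPTL4 at 19.7, 9.6 and 5.69 CPM and NDRG1 at 239.2, 87.1 and 164 CPM. The simulated number for this list was 5 (1 to 9). Of 79 cytosolic ribosomal protein genes, 61 were below the control in both, by small amounts, against a simulated 25.6 (19 to 33). Their median log2 ratios were -0.16 and -0.21 for the labels shRNA 1 and shRNA 2. All 13 mitochondrially encoded mRNAs were below the control in both as well, against a simulated 4.8 (2 to 8), with adjusted p = 0.0943 by camera. This list was called with DESeq2, limma-voom, the likelihood ratio test, no filter and 5 CPM or more, and had adjusted p = 0.988 with an estimated correlation. The simulation leaves out that members of a list vary together, so a deviation of the lone control is not excluded by these numbers. Camera gave adjusted p = 0.00622 for the inflammatory genes, 0.00622 for the hypoxia genes and 0.00366 for the ribosomal proteins. With an estimated correlation each had adjusted p = 0.988.

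The remaining called lists had medians of opposite sign in the shRNA libraries. DNA replication genes had a median log2 ratio of 0.19 in the library labelled shRNA 1 and -0.84 in the library labelled shRNA 2. Of 23 measured members, 2 were below the control in both and 0 above it in both, against a simulated 7.8 and 7.3 (3 to 11 for each). MCM4, a subunit of the replicative helicase, stood at 417.1 CPM in the control and at 424 and 154.4 CPM. Interferon response genes lay at -0.12, percentile 3.7 of random lists, and 0.54. Of 31 measured members, 30 were above the control with the label shRNA 2 and 12 with both labels, against a simulated 10.1 (5 to 16), and 1 was below it in both. MX2 stood at 4.62, 7.04 and 20.5 CPM and IFITM1 at 30.7, 27.7 and 100.7 CPM in the control and the libraries labelled shRNA 1 and shRNA 2. Camera gave adjusted p = 0.0275 for DNA replication and 0.0272 for interferon, and adjusted p = 0.988 for each with an estimated correlation. That estimate was 1 for DNA replication and 0.871 for interferon, far above the preset 0.01 behind these calls.

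**Figure D2:**
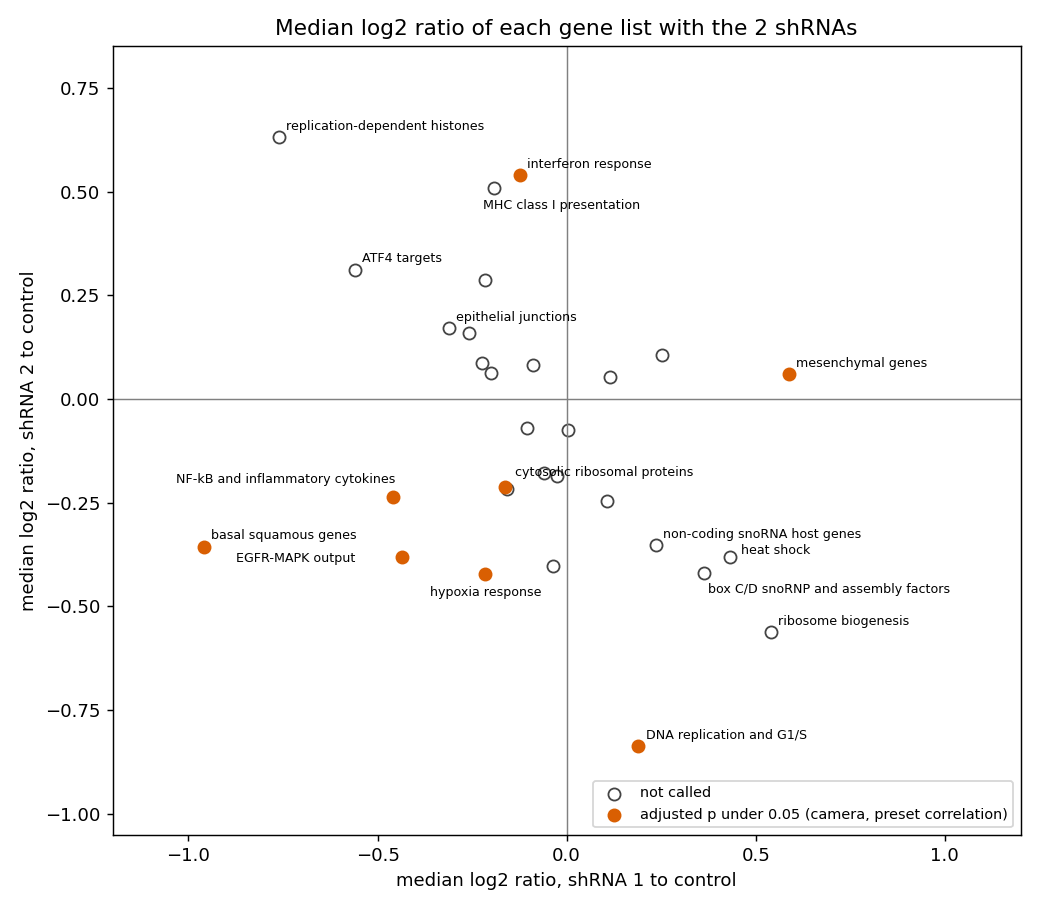
Median log2 ratio of each of 30 gene lists to the control in the library labelled shRNA 1 (horizontal axis) and in the library labelled shRNA 2 (vertical axis). Filled points mark the 8 lists with an adjusted p under 0.05 in camera with a preset correlation. With an estimated correlation, a test on 1 residual degree of freedom, 0 lists kept that call. Basal squamous genes lie at -0.96 and -0.36, and ribosome biogenesis genes at 0.54 and -0.56.

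Components of the PI3K, AKT and mTOR pathway were not called as a group. Of 26 measured members, 11 were above the control in both shRNA libraries, against a simulated 9.1 (3 to 13), and 4 below it in both, with medians of 0.12 and 0.05 and adjusted p = 0.569 by camera. DEPTOR, which encodes an inhibitor of mTOR, had the largest log2 fold change among members with at least 1 CPM, at -1.33 (SE 0.83, adjusted p = 1 by edgeR). It stood at 1.82, 0.3945 and 1.035 CPM, with count ratios to the control of 0.216 (exact interval 0.0733 to 0.533) for the library labelled shRNA 1 and 0.568 (0.296 to 1.06) for the library labelled shRNA 2. PIK3CA, a catalytic subunit of the kinase, stood at 57.6, 72.1 and 82.4 CPM (log2 fold change 0.42, SE 0.33). PPP1CA, a catalytic subunit of protein phosphatase 1, stood at 302.2 CPM in the control and at 262.1 and 313 CPM in the libraries labelled shRNA 1 and shRNA 2, with 26.93% of its exonic bases overlapped on the opposite strand. AKT1 stood at 109.8, 122.1 and 97.9 CPM and MTOR at 123.8, 152 and 104.5 CPM. The translation repressor gene EIF4EBP1 stood at 68.55, 67.7 and 83.65 CPM and the cap-binding gene EIF4E at 38, 55 and 38.1 CPM. The log2 fold change of AKT1 was 0.003 (SE 0.32), and its sign turned under upper-quartile scaling. Protein levels and phosphorylation were not analysed here.

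The shRNA libraries also differed from each other. Between them 2163 genes lay at least 2-fold apart, against 1659 between the library labelled shRNA 1 and the control and 1147 between the library labelled shRNA 2 and the control. CDCA7 stood at 59.7 CPM with the label shRNA 1 and 9.72 CPM with the label shRNA 2, and FABP5, a fatty acid binding protein gene, at 24.4 and 3.97 CPM. S100P stood at 3.35 and 22.2 CPM and CLIC3 at 8.09 and 52.2 CPM in the same order. These are single libraries, and the difference has no replicate check.

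The 10 fibroblast markers summed to 16.3, 9.86 and 13.9 CPM in the control and the libraries labelled shRNA 1 and shRNA 2, nearly all from COL1A1, without which the other 9 had 5, 8 and 11 counts. The 8 endothelial markers summed to 5.21, 3.35 and 6.5 CPM and the 9 leukocyte markers to 6.77, 4.8 and 7.07 CPM. Neuronal genes typical of the 293T cells that packaged the virus summed to 174, 226 and 163 CPM, nearly all from INA, which had 2604, 3341 and 2768 counts.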

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

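The difference between the shRNA libraries was not tested, since each has 1 library. Of the tests in this part, those of depth and GC content by number of calls were set before their results were seen, though repeating the depth test over 10 draws was added later. The others, on 2-fold counts, fibroblast markers, antisense genes, opposite-strand members, keratins and the level of the control, were chosen after the values they rest on had been looked at. For 8 lists the median log2 ratio to the control had opposite signs in the libraries labelled shRNA 1 and shRNA 2, each outside the middle 95 percent of random lists. The median log2 ratio of shRNA 1 to shRNA 2 was 1.02 for ribosome biogenesis, 0.67 for box C/D snoRNP and assembly factors and 0.55 for non-coding snoRNA host genes. NOP56, a core protein of box C/D particles, stood at 129.9 CPM in the control, 244.6 CPM with the label shRNA 1 and 75.8 CPM with the label shRNA 2. The value was 1.03 for DNA replication, 0.83 for heat shock, -0.88 for ATF4 targets, -1.42 for replication-dependent histones and -0.55 for epithelial junctions. HSPA8 stood at 951.9, 1795 and 665.2 CPM, TRIB3 at 88.2, 67 and 188.3 CPM and CLDN1 at 331, 128.9 and 377.5 CPM.

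With the library labelled shRNA 1 in the control's place, edgeR's quasi-likelihood test called 451 genes, against 0 with either other library there, and 873 genes lay at least 2-fold from both others, against 386 and 460. After thinning to equal depth, 10 draws gave 17 to 640 calls with the library labelled shRNA 1 as the single one, which decides nothing because the bound was a multiple of the 0 calls of the others, but at least 810 genes at least 2-fold apart, against at most 494, which argues against depth as the whole cause. After removing trends on GC content and length, 11 calls were made, under the bound set for such a cause, but the call count with the control as the single library moved from 0 to 20 under the same correction, so this count decides nothing. The control as the single library is the comparison of knockdown with control itself. By 2-fold counts, 820 genes were counted after that correction, against 459 for the next library, which argues against GC content and length as the whole cause. Fibroblast markers other than COL1A1, which the control line carries too, summed to 0.526 CPM in this library (exact interval 0.227 to 1.04) while 588 genes lay at least 2-fold below both others, which argues against fibroblast RNA as the whole cause; the shRNA itself, a property of the line and a wrong label stay open and were not tested.

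Antisense genes carried counts of the order that reads of their partners predict, with 46.5 percent within 2-fold. For 282 antisense genes lying at least 90 percent inside exons of an opposite gene, the median count was 1.58 times what the partner's reads per base predict (quartiles 0.737 and 2.34). This is what reads without strand information would give. Antisense transcription in its own right stays open: the log2 ratios of shRNA 1 to control of gene and partner had r = 0.727 across 262 pairs (interval 0.664 to 0.779), and the interval spans 0.7, the value above which this was to be argued against.

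Basal squamous and EGFR-MAPK genes lay lower with both shRNAs. Among members with at most 10 percent of exonic bases overlapped, the highest of the 4 medians was -0.33, and without keratins the higher of the basal squamous medians was -0.30 (bootstrap interval -0.97 to -0.10, 7 members), which argues against opposite-strand reads and shared keratin reads as the whole cause. A high level in the 1 control library cannot be told apart from an effect of the shRNAs for either list. The EGFR-MAPK median of shRNA 1 to shRNA 2 lay at percentile 33.97 of random lists, which either would give. The basal squamous median of shRNA 1 to shRNA 2 was -0.84, at percentile 0 and further from 0 than a high control alone would give, but its bootstrap interval over 13 members, -1.45 to 0.10, includes 0.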

How the results depend on the processing

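The settings with library sizes of filtered genes, without opposite-strand overlap and with thinned counts, and the 2-fold counts with 1 shRNA line left out, were chosen after the data were seen. No paired analysis was possible because the control has 1 library and the groups share only the number 1. The genes lower in SNORD12B knockdown numbered 0 in edgeR's quasi-likelihood test, 1 with upper-quartile factors, 1 with total counts, 14 with DESeq2, 1 with limma-voom, 36 with the likelihood ratio test and 37 with no filter. The genes higher in SNORD12B knockdown numbered 0, and 2 and 4 with the last of these. Removing trends on GC content and length moved the calls in this comparison too, as given above. The gene lists called numbered 8, and 13 with DESeq2, 11 with limma-voom and 11 with the likelihood ratio test. They numbered 12 at 5 CPM or more, 4 with no filter, 0 with an estimated correlation and 0 with fry. Ribosomal protein, basal squamous and EGFR-MAPK genes were called in the same direction in 10 of 10 planned settings with the preset correlation, and the other called lists in 9, lost with no filter. The planned change of library size left the list values as they were, and the changes of scaling hardly moved them. Those settings thus add little to these counts. For EGFR-MAPK, hypoxia, ribosomal protein and mesenchymal genes the estimated correlation was -0.042, -0.055, 0 and 0, below the preset one. Their higher p with it thus does not come from the size of the estimate. Both the estimate and that test rest on 1 residual degree of freedom, the difference between the 2 shRNA lines. The estimate therefore cannot show whether members vary together in the lone control. For the other called lists the estimate lay above the preset one, at 1 for DNA replication and 0.871 for interferon genes. It was 0.083 for inflammatory and 0.077 for basal squamous genes. The cause of the other differences was not tested.

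The genes at least 2-fold higher with both shRNAs numbered 174 and the genes at least 2-fold lower with both shRNAs 212. They numbered 468 and 1020 with no filter, 18 and 36 at 5 CPM or more, 31 and 103 with a prior count of 10, and 581 and 618 at a fold of 1.5. With 1 shRNA line left out they lay at 531 to 665 higher and 616 to 994 lower. The correlation of the 2 shRNA log2 ratios, 0.34, was 0.182 at 5 CPM or more and 0.291 with a prior count of 10. Fewer genes were tested at 5 CPM or more, and the cause of the other differences was not tested.

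Of 1581 values of 161 named genes under the other settings, 1526 kept direction and side of the threshold, 47 newly passed and 8 turned sign. With 1 line left out, a value with no test, 51 of 322 values of these genes turned sign. Where the lines differ in sign, as a rule only 1 value per gene can turn. The 51 are thus to be read against the 161 genes. By more than 1 SD between the lines, 8 values moved. Each line lies less than 1 SD from the mean of the lines by construction, so hardly any value can pass this bound. The count of 8 thus does not show that the values are stable. None of these genes had passed the adjusted threshold in edgeR's quasi-likelihood test. The log2 fold change of AKT1 turned to -0.009 with upper-quartile factors, -0.007 with limma-voom and -0.007 with no filter, and the log2 fold change of LAPTM5 to 0.001 with total counts. With limma-voom the log2 fold change of SNORD12B turned to -0.80, the log2 fold change of CDH5 to -0.23, the log2 fold change of FABP5 to -0.23 and the log2 fold change of S100P to -0.37. Leaving out 1 line turned the DNA replication median (-0.84 to 0.19) and the interferon median (-0.12 to 0.54). The cause was not tested.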

Other observations

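Among the fixed lists that camera did not call on log-CPM in the main setting, mitosis genes lay mostly above the control. Of 24 mitosis genes, 14 were above the control in both shRNA libraries and 1 below it in both, including CENPF at 131.8, 201.4 and 181.4 CPM in the control and the libraries labelled shRNA 1 and shRNA 2 (adjusted p = 0.0684 by camera; simulated unchanged libraries gave 7.7, range 3 to 13, above in both). Of 25 cholesterol synthesis genes, 11 were below in both and 2 above in both, against a simulated 8.5 (5 to 13) below (adjusted p = 0.162). Of 31 respiratory chain genes, 19 were below in both and 0 above in both, against a simulated 10.1 (5 to 16) below. Glycolysis genes had adjusted p = 0.0684, respiratory chain genes 0.146, YAP targets 0.41, MHC class I genes 0.471, ER chaperones 0.478, other TOP mRNAs 0.569, matrix proteases 0.713, p53 targets 0.805, apoptosis regulators 0.805, keratinocyte differentiation 0.814 and NRF2 targets 0.814, all by limma's camera. With other settings and the preset correlation, camera called mitosis and glycolysis genes with DESeq2 (adjusted p = 0.00398 and 0.00319), limma-voom (0.00398 and 0.0123), the likelihood ratio test (0.0279 for both) and 5 CPM or more (0.014 and 0.0272), against adjusted p = 0.988 for both with an estimated correlation. It also called cholesterol synthesis genes with DESeq2 (adjusted p = 0.0136) and 5 CPM or more (0.0374), and respiratory chain genes with DESeq2 (0.0193). These lists too had adjusted p = 0.988 by camera with an estimated correlation. Among YAP targets, CCN2, a secreted matricellular protein gene, stood at 148.9, 68.65 and 21.5 CPM, and was called lower by edgeR's quasi-likelihood test with no filter. Uncalled lists whose medians differed in sign between the shRNA libraries, each outside the middle 95 percent of random lists, had adjusted p = 0.999 for box C/D snoRNP factors, 0.976 for snoRNA host genes, 0.814 for ribosome biogenesis, 0.478 for ATF4 targets, 0.805 for heat shock, 0.713 for histones and 0.713 for epithelial junctions by camera. Median, mean and test differed in sign for 4 lists, for each of which camera gave the direction down. The median and mean log2 fold changes were 0.09 and -0.13 for matrix proteases, 0.11 and 0.03 for histones, 0.01 and 0.08 for box C/D snoRNP factors and -0.03 and 0.06 for snoRNA host genes.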
